A study of Mus musculus with 36 samples.

How the data were processed

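Thymocyte RNA was measured by sequencing of polyadenylated RNA in 36 libraries, 3 for each of 12 groups (CD4 or CD8 lineage, SM, M1 or M2 subset, KO or WT), from mice 4 weeks old. Per the labels' protocols, RNA was extracted with TRIzol and an RNeasy kit and libraries were made with a strand-specific KAPA kit. Groups and replicate numbers were taken from the sample labels. The strain label of the KO libraries names a targeted Psmb11 allele on a B6 background.

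Per the submitters' processing notes, bcl2fastq 2.17, STAR 2.5.1b and RSEM 1.2.28 were used. Their order and settings are not given in the sources used here. The authors deposited, for each library, a gene count file of STAR (whole-number counts of reads per gene, not normalized, in columns 2 to 4 by strand) and a gene file of RSEM with expected counts (estimated counts that need not be whole). The genome build label names a human assembly, GRCh38, although every gene identifier is a mouse one, so the build used is uncertain. Gene names and coordinates came from the GENCODE M21 annotation of GRCm38, in which 47224 of 47643 identifiers (99.1%) were found. Column 4 of the STAR files was used, since it held 17.7 to 22.8 times as many gene counts as column 3, the other strand. The 4 lines of each STAR file that name no gene were left out of library sizes and tests. They held 19.3 to 37.7% of the total: 2.42 to 15.0% unmapped, 4.12 to 6.75% multimapping, 8.62 to 22.8% with no feature and 1.08 to 1.51% ambiguous. Multimapping reads are not in the counts, which lowers genes with near-identical copies. Of the RSEM files, 8 have 11 columns and 28 have 17. The RSEM expected counts were rounded to whole numbers for an alternative, and correlated with the STAR counts across genes at 0.978 to 0.983.

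Gene counts per library were 23589863 to 39758448, and RSEM totals were 0.942 to 0.995 times as large. The 10 most abundant genes took 4.17 to 5.72% of the counts. A level of 3 counts, used as the floor, stood for 0.0755 to 0.127 CPM before TMM scaling. Reads without molecular identifiers are not independent molecules, so this floor covers counting error only. The first 3 principal components of log2 CPM held 35.2, 21.5 and 5.91% of the variance. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom 4.82 to 66.5 over 36 pairs), so each counted as 1 replicate.

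The following choices were made before the data were examined. Genes with enough counts in the 12 groups (edgeR filterByExpr) were kept, which left 15981. Library sizes were scaled by TMM, and a single quasi-likelihood model (glmQLFit, glmQLFTest, edgeR 4.0.16, limma 3.58.1, R 4.3.3) with 1 mean per group was fitted to all libraries, so that groups shared the estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was its size over the square root of the F statistic. The 16 comparisons were KO against WT in 6 subsets, 3 interactions (CD8 minus CD4 difference in the KO effect at SM, M1 and M2), 4 stage comparisons in WT and 3 lineage comparisons in WT. CPM levels were counts over the library size scaled by TMM. Fold changes used the default prior count of edgeR, and log2 CPM a prior count of 2. No exact test of 3 against 3 libraries can give a p under 0.1, so single genes were tested only in the model across all genes.

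Of the 34 fixed gene lists, 23 describe functions and 11 mark other cell types or sex. The function lists were antioxidant, chaperone, unfolded protein and integrated stress response, apoptosis promoter and inhibitor, TCR response, trafficking, immature and mature single positive, interferon-stimulated, CD4 lineage, CD8 lineage and cytotoxic, innate-like and memory, WNT and TCF1, constitutive proteasome, immunoproteasome and MHC class I, cell cycle, p53 target, oxidative phosphorylation, mitochondrial genome, glycolysis and hypoxia, ribosomal protein and immediate early genes. The others were markers of thymic epithelial cells, B cells, dendritic cells and MHC class II, macrophages, granulocytes, erythroid cells, double positive thymocytes, gamma delta T cells, NK and innate lymphoid cells and regulatory T cells, and sex-linked genes. Each of 32 lists was tested in the 6 subsets with camera of limma at a preset correlation of 0.01, adjusted over the 192 tests. Of the 77 list calls, 18 held with an estimated correlation. Genes were named by rule. In each KO comparison these were Psmb11 and the 8 higher and 8 lower called genes with the largest change, an average log2 CPM of at least 1 and no overlap between KO and WT libraries (chance gives no overlap in 10% of genes at 3 against 3). In the other comparisons they were the 5 largest in each direction, with no limit on overlap for interactions. In each list they were up to 4 called members with the smallest adjusted p. Predicted genes, pseudogenes, unnamed clones and antigen receptor segments were not named, and segments were counted as groups. Cd4, Cd8a, Cd8b1, Zbtb7b and Runx3 were read as lineage checks and Cd24a, Cd69, Ccr7, S1pr1, Klf2 and H2-Q7 as stage checks. Results of some genes that these rules name are not reported here.

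The alternatives chosen beforehand were RLE size factors, no filter, RSEM counts, the replicate number as a block, only the libraries of the groups compared, DESeq2 1.42.0, each library left out, an estimated correlation and fry. Alternatives chosen after seeing the data were a GC content correction, the same with the block, a term for 5 libraries and their removal. For the GC correction each library's counts were scaled along a spline (5 degrees of freedom) of log2 counts on gene GC content. The 5 libraries were those with a GC slope below -0.2 per 10 percentage points, over 9301 genes, a limit also set after seeing the data. Their unmapped reads were 4.85 to 15.0% against 2.42 to 4.71% in the other 31, and mitochondrial genes held 2.02 to 2.72% against 0.903 to 2.01% of counts. Only CD4 SM KO holds libraries both in and outside the 5, so the term is estimated from that group alone, with its replicate 3 as the single library outside. In comparisons with CD4 M2 of WT the term carries this difference over, and it cannot test the genes there.

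Whether replicate numbers pair libraries was checked by correlating deviations from the group means over 9298 genes, with every pair above 0.1 taken as pairing. KO and WT paired in CD4 M2 (0.17, 0.33 and 0.10) and in no other subset. Both genotypes paired between lineages at M1 (0.25, 0.34 and 0.47 in KO, 0.31, 0.16 and 0.44 in WT). WT also paired between SM and M1 in CD4 (0.23, 0.12 and 0.14) and in CD8 (0.42, 0.48 and 0.43), between M1 and M2 in CD8 (0.35, 0.41 and 0.53) and between lineages at SM (0.27, 0.33 and 0.50), and KO between lineages at M2 (0.35, 0.36 and 0.38). The labels do not say what a number stands for, and over all 15981 genes only M1 against SM in WT CD8 met the limit.

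The tests were checked on simulated counts of KO and WT in CD8 M1 over 15981 genes. Of 50 genes changed at each size, 39 were recovered at 1.5-fold, 45 at 2-fold and 50 at 4-fold and 8-fold, and 4 of 15761 unchanged genes were called. With a simulated GC slope of -0.4, 2670 unchanged genes were called without the GC correction and 9 with it. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.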

Results

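Polyadenylated RNA was sequenced from thymocytes of 4-week-old mice, in libraries labelled wild type (WT) or Psmb11-deficient (KO). Psmb11 encodes a catalytic subunit of the thymoproteasome, the proteasome variant of cortical thymic epithelial cells that cuts the peptides on which developing CD8 T cells are positively selected. The thymocytes came from the CD4 and the CD8 lineage. Within each lineage the labels name maturation subsets SM, M1 and M2 and do not expand these abbreviations. The 6 subsets of both genotypes gave 12 groups of 3 libraries, 36 libraries in all. Each library held 23589863 to 39758448 reads assigned to genes, and 16507 to 20324 genes had at least 1 count. The design asks which genes differ between the genotypes in each subset. Cortical and medullary thymic epithelial cells, which the series title also names, were not analysed here. Levels are in CPM (counts scaled to a common library size), as mean ± SD of 3 libraries. Log2 fold changes of KO against WT are given ± SE, with Benjamini-Hochberg adjusted p from the quasi-likelihood test of edgeR. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

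The targeted gene itself was read in every group, at a low level that was higher in the libraries labelled KO. Psmb11 (ENSMUSG00000072423.4, chromosome 14, 54621433 to 54629556, plus strand, in the GRCm38 annotation) had 0.553 ± 0.239 against 0.131 ± 0.131 CPM in CD4 SM (adjusted p = 0.029). It had 0.745 ± 0.269 against 0.101 ± 0.102 CPM in CD4 M1 (adjusted p = 0.048) and 0.648 ± 0.296 against 0.12 ± 0.0338 CPM in CD4 M2 (adjusted p = 0.0066). In the CD8 lineage it had 0.756 ± 0.188 against 0.0581 ± 0.0596 CPM in SM (adjusted p = 7.5e-04). Its levels were 0.995 ± 0.28 against 0.117 ± 0.0335 CPM in M1 (adjusted p = 0.0093) and 0.9 ± 0.252 against 0.0107 ± 0.0185 CPM in M2 (adjusted p = 2.2e-04). These levels stand for 7 to 47 counts per KO library and 0 to 8 per WT library, beside a limit of 0.0755 to 0.127 CPM that 3 counts set, which covers counting error only. The files do not say which part of the gene the counts cover, so the level does not check the loss of the protein. The genotype below is that of the library labels. Without single libraries the call in CD4 SM was lost (log2 fold change 1.60 to 1.73 without KO replicate 1, WT replicate 1 or WT replicate 3). In CD4 M1 it was lost without any library but KO replicate 2 (2.29 to 3.76), and in CD8 M1 without WT replicate 1.

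In the CD8 SM subset, genes of the CD4 lineage, of the response to T cell receptor (TCR) signals and of the cell cycle rose in KO libraries, and genes of the CD8 lineage and interferon-stimulated genes fell. Cd4, the coreceptor for MHC class II, rose from 690.1 ± 67.1 to 1234 ± 76.1 CPM (log2 fold change 0.84 ± 0.12, adjusted p = 9.0e-06). Zbtb7b, the transcription factor that commits thymocytes to the CD4 lineage, rose from 88.9 ± 3.99 to 233 ± 58.6 CPM (1.39 ± 0.14, adjusted p = 4.9e-08). Gata3, which acts upstream of Zbtb7b, rose by 0.79 ± 0.08 on the log2 scale. Of the 6 CD4 lineage genes tested, 5 rose and 1, Tnfsf8, fell (log2 fold change -1.39 ± 0.25), with the same numbers adjusted over the list alone (camera, adjusted p = 3.0e-11). Of the 14 CD8 lineage and cytotoxic genes, 5 fell and 1 rose (6 and 2 adjusted over the list alone, camera, adjusted p = 1.8e-05). Among those that fell was Itgae, an integrin of CD8 T cells (3.26 ± 0.503 against 11.2 ± 2.94 CPM). Others were the cytotoxic granule genes Nkg7 (-1.35 ± 0.22) and Ctsw (-0.88 ± 0.09), and Runx3, the transcription factor of the CD8 lineage (-0.54 ± 0.08). Of the 22 genes that respond to TCR signals, 13 rose and 0 fell (15 and 0 adjusted over the list alone, camera, adjusted p = 7.5e-11). They included Cd5 (874 ± 9.73 against 476 ± 29.6 CPM), a surface inhibitor whose level follows signal strength, and Nr4a1 (0.89 ± 0.17). Of the 12 markers of immature single positive cells, 8 rose (also 8 adjusted over the list alone, adjusted p = 3.9e-11). Examples were Rag1, a subunit of the recombinase of receptor gene assembly (574 ± 87.2 against 322 ± 20.4 CPM), Itm2a (0.83 ± 0.13), Tox (0.58 ± 0.07) and Tox2 (1.04 ± 0.19). Markers of double positive thymocytes, a cell type that the gate could also hold, moved with them. Of these, 3 of 7 rose (5 adjusted over the list alone, adjusted p = 0.0028, and adjusted p = 0.22 with an estimated correlation). The lists share members, so here and in the subsets below they are not separate evidence. Rag1 and Rag2 are in the immature and double positive lists. Cd5, Cd69, Egr1 and Nr4a1 are in the immature and TCR response lists, and Tox in the immature and CD4 lineage lists.

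Interferon-stimulated genes were lower in CD8 SM of KO libraries. Of the list, 15 of 26 fell and none rose (16 adjusted over the list alone, camera, adjusted p = 1.0e-12, and adjusted p = 0.063 with an estimated correlation). Oas2, an antiviral oligoadenylate synthetase, fell from 22.9 ± 3.56 to 11.8 ± 2.27 CPM. Xaf1 had a log2 fold change of -0.76 ± 0.10, and Ddx58, a sensor of viral RNA, one of -0.44 ± 0.07. Of 23 cell cycle genes, 16 rose (21 adjusted over the list alone, adjusted p = 2.8e-12, and adjusted p = 0.18 with an estimated correlation). Among them were the mitotic kinase Plk1 (0.81 ± 0.17), cyclin Ccnb2 (0.80 ± 0.17) and Tyms (0.72 ± 0.12), which makes thymidylate. Of 27 antioxidant genes, 13 rose (15 and 1 lower adjusted over the list alone, adjusted p = 2.1e-04, and adjusted p = 0.23 with an estimated correlation). One was G6pdx (0.40 ± 0.09), which supplies NADPH. Glycolysis and hypoxia genes rose in 8 of 19 cases, such as Slc2a3 (0.45 ± 0.08). Of that list 1 gene fell, Pdk1 (-0.69 ± 0.08), a kinase that holds pyruvate back from the mitochondria (12 higher and 1 lower adjusted over the list alone, adjusted p = 0.0016, and adjusted p = 0.38 with an estimated correlation). Among trafficking receptors 6 of 15 rose, such as Gpr183 (1.29 ± 0.25) and Ccr4 (0.79 ± 0.15), and 2 fell (8 higher and 2 lower adjusted over the list alone, adjusted p = 0.037, and adjusted p = 0.31 with an estimated correlation). Apoptosis promoters rose in 6 of 23 cases, Bak1 by 0.42 ± 0.09, and fell in 1 (8 higher and 2 lower adjusted over the list alone, adjusted p = 0.024, and adjusted p = 0.14 with an estimated correlation). Lef1 (0.59 ± 0.07) was among 5 of 14 WNT and TCF1 pathway genes that rose, a list that was not called (camera, adjusted p = 0.068). In all, 1348 genes were higher and 1081 lower in CD8 SM (2429 of 15981 tested). The count fell to 904 without KO replicate 1 and to 885 without WT replicate 2. With a GC content correction 1865 genes were higher and 873 lower, 2007 of them also called without it.

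In CD8 M1, CD4 lineage genes and TCR response genes were again higher in KO libraries, and proliferation genes were lower. Cd4 had 32.5 ± 9.07 against 12.4 ± 1.22 CPM (log2 fold change 1.39 ± 0.13, adjusted p = 4.0e-08). Zbtb7b had 3.44 ± 1.18 against 0.697 ± 0.165 CPM (2.28 ± 0.29, adjusted p = 3.7e-05). In all, 3 of 6 CD4 lineage genes rose (5 adjusted over the list alone, camera, adjusted p = 4.6e-15). Of 22 TCR response genes, 7 rose (13 adjusted over the list alone, adjusted p = 1.2e-09). They included the costimulatory receptor Tnfrsf9 (209 ± 8.37 against 130.5 ± 4.05 CPM), Nr4a3 (0.48 ± 0.09) and Bcl2l11 (0.51 ± 0.10), which promotes the death of thymocytes with strong signals. Immature single positive markers rose in 4 of 12 cases (7 adjusted over the list alone, adjusted p = 1.6e-07). Mki67, the proliferation antigen, fell from 597 ± 86.01 to 296 ± 28.7 CPM (-1.01 ± 0.19, adjusted p = 0.0028). The spindle checkpoint kinase Bub1 and the kinetochore gene Cenpf had log2 fold changes of -0.84 ± 0.15 and -1.20 ± 0.19. Of 23 cell cycle genes, 7 fell and none rose (22 adjusted over the list alone, adjusted p = 2.0e-20, and adjusted p = 0.066 with an estimated correlation). Myo1e, a class I myosin, rose from 1.09 ± 0.278 to 4.04 ± 0.296 CPM (1.89 ± 0.25). Atp8b4, a phospholipid flippase, had 35.7 ± 5.78 against 74.3 ± 5.30 CPM (-1.06 ± 0.16). Markers of other cells moved with these groups. Regulatory T cell markers rose in 4 of 9 cases (6 adjusted over the list alone, adjusted p = 5.5e-09). Double positive markers rose in 1 of 7 (3 higher and 0 lower adjusted over the list alone, adjusted p = 9.5e-05, and adjusted p = 0.090 with an estimated correlation). Dendritic cell and MHC class II markers rose in 1 of 6 (Cd74, 64.6 ± 3.56 against 37.9 ± 3.47 CPM, adjusted p = 4.5e-06). In all, 151 genes were higher and 213 lower (364 called). The count was 100 without KO replicate 1, 176 without KO replicate 2 and 162 without KO replicate 3. It was 101 without WT replicate 1, 103 without WT replicate 2 and 218 without WT replicate 3. With a GC content correction 174 genes were higher and 161 lower, 271 of them also called without it.

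In CD8 M2, TCR response genes rose in KO libraries together with genes of innate-like T cells and of natural killer (NK) cells. Nrgn, a calmodulin-binding protein, rose from 2.21 ± 0.324 to 14.6 ± 3.11 CPM (2.72 ± 0.28, adjusted p = 1.2e-07). Myo1e rose from 0.768 ± 0.0932 to 5.10 ± 1.40 (2.72 ± 0.26, adjusted p = 8.0e-08). Spry2, a feedback inhibitor of growth factor signals, rose from 1.55 ± 0.523 to 10.5 ± 1.71 (2.74 ± 0.30) and Lgals3, a galectin, from 1.996 ± 0.646 to 8.17 ± 0.307 (2.05 ± 0.24). Of 22 TCR response genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone, adjusted p = 2.0e-08). They included the inhibitory receptor Pdcd1 (17.8 ± 2.10 against 8.67 ± 0.501 CPM), Tnfrsf9 (0.85 ± 0.13) and Tagap (1.02 ± 0.20). Immature markers rose in 6 of 12 cases (9 adjusted over the list alone, adjusted p = 1.2e-08), such as Cd24a (37.7 ± 6.47 against 21.5 ± 1.54 CPM) and Cd69 (0.74 ± 0.15). Innate-like and memory T cell genes rose in 3 of 14 cases (3 higher and 0 lower adjusted over the list alone, adjusted p = 8.1e-05). The chemokine Ccl5, a member of that list and of the cytotoxic list, rose from 1.24 ± 0.334 to 7.14 ± 1.51 CPM (2.52 ± 0.42). NK and innate lymphoid cell markers rose in 2 of 3 cases (3 adjusted over the list alone, adjusted p = 1.4e-05). One of them was Fcer1g, an adaptor of activating receptors (3.28 ± 1.21 against 0.417 ± 0.274 CPM). Of 7 markers of gamma delta T cells, 1, Tcrg-C2, one of a family of similar genes whose reads may be split, rose (11.7 ± 3.58 against 2.30 ± 0.2 CPM) and 1, Cd163l1, fell (5 and 1 adjusted over the list alone, adjusted p = 7.1e-04). The Cd163l1 call was lost without KO replicate 1, KO replicate 3, WT replicate 1 or WT replicate 2 (log2 fold change -1.22 to -0.77). Cd4 was 8.47 ± 1.83 against 3.85 ± 0.646 CPM (1.13 ± 0.16, adjusted p = 4.0e-05). Among the lists of lineage genes, 2 of 6 CD4 lineage genes rose (4 adjusted over the list alone, adjusted p = 5.0e-05). Double positive markers rose in 3 of 7 cases (7 adjusted over the list alone, adjusted p = 1.8e-07). One was Dntt, the enzyme that adds untemplated nucleotides to receptor genes (60.5 ± 5.29 against 34.9 ± 1.39 CPM). Regulatory T cell markers rose in 4 of 9 (4 higher and 0 lower adjusted over the list alone, adjusted p = 1.7e-04, and adjusted p = 0.052 with an estimated correlation). Foxp3 stood at 11.2 ± 4.30 against 5.26 ± 0.246 CPM. In all, 244 genes were higher and 267 lower (511 called). The count was 113 without KO replicate 1 (101 higher and 12 lower), 1206 without KO replicate 2 and 169 without KO replicate 3. It was 143 without WT replicate 1, 138 without WT replicate 2 and 216 without WT replicate 3. With a GC content correction 242 genes were higher and 122 lower, 304 of them also called without it. The Foxp3 call was lost without KO replicate 1, WT replicate 1 or WT replicate 2 (log2 fold change 0.81 to 1.08).

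**Figure D1:**
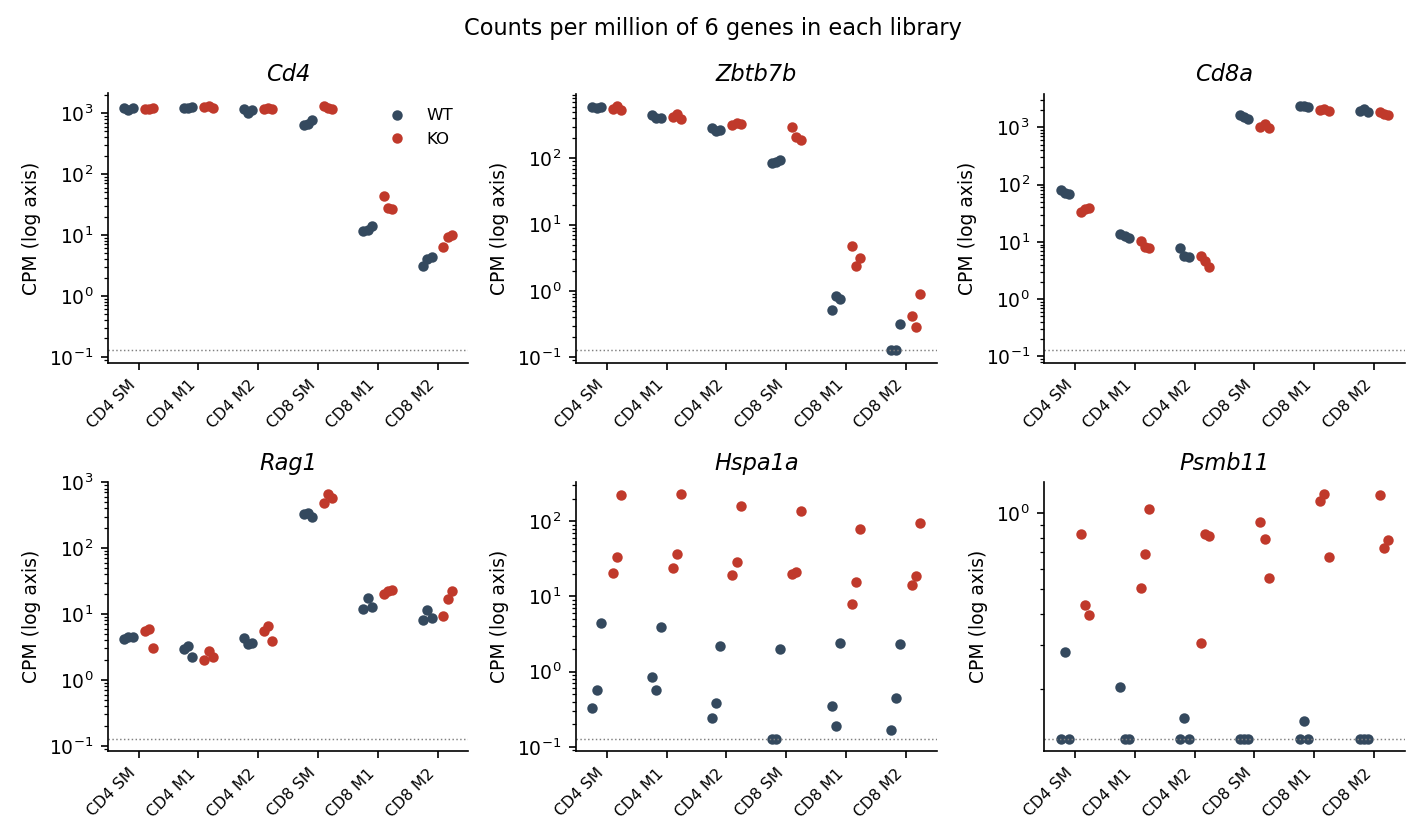
CPM of Cd4, Zbtb7b, Cd8a, Rag1, Hspa1a and Psmb11 on log axes, by thymocyte subset, with 1 point per library (WT dark blue, KO red). The dotted line marks 0.127 CPM, the level of 3 counts in the library with the fewest counts, and values below it are drawn on it. Cd4 in the 3 CD8 subsets and Hspa1a in all 6 subsets lie higher in every KO library than in every WT library of the same subset.

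In CD4 SM, chaperones, immediate early genes and regulators of cell survival were higher in KO libraries, and the CD8 coreceptor genes and cytotoxic genes were lower. With an estimated correlation camera gave the chaperone and immediate early lists adjusted p = 0.40 and 0.39. Cd8a fell from 72.6 ± 6.19 to 36.6 ± 2.79 CPM (-0.99 ± 0.11, adjusted p = 1.4e-06, -0.99 with the GC correction). Cd8b1 fell from 68.1 ± 7.03 to 37.2 ± 4.70 (-0.87 ± 0.11, -0.75 with the correction). In all, 5 of 14 CD8 lineage and cytotoxic genes fell (5 adjusted over the list alone, adjusted p = 2.2e-08). Nr4a2, an orphan nuclear receptor (56.3 ± 35.2 against 13.2 ± 1.41 CPM), and Hey1, a target of Notch (32.6 ± 16.6 against 8.66 ± 3.23 CPM), rose. So did Klf2, which drives thymic exit (52.5 ± 31.2 against 18.996 ± 3.66 CPM), and Cxcr4 (43.5 ± 17.04 against 16.7 ± 6.98 CPM). Their log2 fold changes were 2.09 ± 0.39, 1.92 ± 0.33, 1.47 ± 0.30 and 1.38 ± 0.28, and 2.11, 2.05, 1.65 and 1.35 with the GC correction. Of 18 p53 target genes 5 rose, Pmaip1 by 2.33 ± 0.39 and Gadd45a by 0.83 ± 0.18, and 2 fell (8 higher and 3 lower adjusted over the list alone, adjusted p = 0.024, and adjusted p = 0.16 with an estimated correlation). Apoptosis inhibitors rose in 7 of 21 cases, such as Birc2 (0.57 ± 0.11), and fell in 1 (8 higher and 1 lower adjusted over the list alone, adjusted p = 0.037, and adjusted p = 0.14 with an estimated correlation). Cell cycle genes fell in 8 of 23 cases, such as Mcm3 (-0.57 ± 0.13) and Mcm5 (-0.51 ± 0.12), and rose in 1 (1 higher and 8 lower adjusted over the list alone, adjusted p = 3.3e-04, and adjusted p = 0.50 with an estimated correlation). Mitochondrial genome transcripts rose in 8 of 13 cases with a median log2 fold change of 0.88 (9 higher and 0 lower adjusted over the list alone, adjusted p = 9.0e-07, and adjusted p = 0.18 with an estimated correlation). The number and median were 3 and 0.39 with the GC correction and 0 and -0.19 with a term for 5 libraries that stand apart, where the list had adjusted p = 0.0077 and 0.16. Those 5 libraries, KO replicates 1 and 2 of CD4 SM and the 3 WT libraries of CD4 M2, had counts that fell with the GC content of the gene, more unmapped reads and more mitochondrial reads than the other 31. Nuclear oxidative phosphorylation genes fell in 15 of 32 cases, rose in 1, and fell in 1 with the GC correction (1 higher and 19 lower adjusted over the list alone, adjusted p = 8.1e-05, adjusted p = 0.52 with an estimated correlation, 2.0e-05 with the GC correction and 4.2e-07 with the term). Immunoproteasome and MHC class I genes fell in 7 of 14 cases and 0 with the GC correction (1 higher and 9 lower adjusted over the list alone, adjusted p = 0.0023, adjusted p = 0.38 with an estimated correlation, 0.28 with the GC correction and 0.0013 with the term). Ribosomal protein genes fell in 4 of 22 cases and 0 with the GC correction (0 higher and 6 lower adjusted over the list alone, adjusted p = 5.5e-04, adjusted p = 0.62 with an estimated correlation, 0.0079 with the GC correction and 4.6e-04 with the term). Glycolysis and hypoxia genes fell in 5 of 19 cases and rose in 1, Vegfa, whose call was lost without KO replicate 3 at a log2 fold change of 0.74 (1 higher and 8 lower adjusted over the list alone, adjusted p = 0.027, adjusted p = 0.50 with an estimated correlation, and 0.47 with the GC correction). In all, 1670 genes were higher and 1359 lower (3029 called). With the GC correction 770 were higher and 239 lower (1009 called, 784 of them shared). With the term 143 were higher and 33 lower (176 called, 145 shared). Without the 2 KO libraries among the 5, which left 1 KO against 3 WT libraries with the spread taken from the other groups, 221 genes were called. The count was 1073 without KO replicate 1, 1882 without KO replicate 2 and 1908 without WT replicate 2. Without KO replicate 3, the KO library of this subset outside the 5, it was 4461.

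In CD4 M1, the fewest genes were called of the 6 subsets: 37 genes were higher and 15 lower in KO libraries (52 called, 1721 at an unadjusted p under 0.05). The higher genes held chaperones, transcription factors of the immediate early response and stress genes. Cd8a was among the lower ones (8.67 ± 1.33 against 12.8 ± 0.871 CPM, -0.56 ± 0.12, adjusted p = 0.041). Klf4 rose from 3.21 ± 1.43 to 14.4 ± 9.47 CPM (2.16 ± 0.48, adjusted p = 0.041). Klf6 rose from 82.9 ± 29.1 to 250.1 ± 109 (1.59 ± 0.35). Dnaja1, a partner of Hsp70, rose from 180.04 ± 18.2 to 277 ± 43.1 (0.62 ± 0.12). Ddit3, a transcription factor of the unfolded protein response, had 52.2 ± 7.76 against 37.1 ± 3.51 CPM (0.49 ± 0.11). It was the single member of 13 in that list to pass alone (6 adjusted over the list alone, camera, adjusted p = 3.8e-05, and adjusted p = 0.052 with an estimated correlation). Jrk had the smallest adjusted p (0.0033), with 3.44 ± 0.392 against 7.48 ± 0.885 CPM (-1.12 ± 0.17). Myh10, a nonmuscle myosin, had 3.64 ± 0.996 against 8.10 ± 1.47 CPM (-1.15 ± 0.21). None of 23 cell cycle genes passed the test singly (edgeR, also none adjusted over the list alone). Camera called the list lower at a median of -0.31 (0 higher and 0 lower adjusted over the list alone, adjusted p = 5.0e-08, and adjusted p = 0.33 with an estimated correlation). Cd40lg was the 1 CD4 lineage gene of 6 to rise (2 adjusted over the list alone, adjusted p = 0.042, and adjusted p = 0.18 with an estimated correlation). Cd8a was the 1 CD8 lineage gene of 14 to fall (0 higher and 1 lower adjusted over the list alone, adjusted p = 0.018, and adjusted p = 0.26 with an estimated correlation). Pmaip1 was the 1 p53 target of 18 to rise (4 adjusted over the list alone, adjusted p = 0.0037, and adjusted p = 0.071 with an estimated correlation). Each of the 23 genes named by rule in this comparison lost its call without at least 1 library. The log2 fold changes were then 1.48 to 2.40 for Klf4, 1.22 to 1.62 for Klf6, 0.52 to 0.64 for Dnaja1 and -1.005 to -0.95 for Myh10. edgeR called 0 genes without KO replicate 1 (1112 at an unadjusted p under 0.05), 161 without KO replicate 2, 12 without KO replicate 3, 1 without WT replicate 1 and 16 without WT replicate 2. DESeq2 called 123 over all libraries.

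In CD4 M2, immediate early genes, TCR response genes and some unfolded protein and integrated stress response genes were higher in KO libraries. Mitochondrial transcripts were lower. The 3 WT libraries of this comparison all belong to the 5 that stand apart. The immediate early factor Klf4 had 12.05 ± 8.78 against 2.56 ± 0.9 CPM (2.24 ± 0.50, adjusted p = 8.7e-04, 2.01 with the GC correction) and Fosb 18.01 ± 11.7 against 3.96 ± 2.21 CPM (2.18 ± 0.50, 1.91 with the correction). Ddit3 rose by 0.65 ± 0.11 (0.82 with the correction) and Ppp1r15a, which restores translation after stress, by 1.31 ± 0.29 (1.03). In all, 4 of 13 unfolded protein and integrated stress response genes rose and 1 fell (4 higher and 1 lower adjusted over the list alone, adjusted p = 0.042, adjusted p = 0.37 with an estimated correlation, and 0.067 with the GC correction). Of 22 TCR response genes 8 rose and 1 fell, and 4 rose with the correction (8 higher and 1 lower adjusted over the list alone, adjusted p = 0.011, adjusted p = 0.090 with an estimated correlation, 0.020 with the GC correction and 0.010 with the term). Nfkbid (0.71 ± 0.09), Tagap (1.02 ± 0.20) and Cd6 (0.32 ± 0.07) rose in both. Interferon-stimulated Ifit1 fell from 198 ± 23.98 to 93.9 ± 7.90 CPM (-1.07 ± 0.13, -0.78 with the correction), while its list, with 6 lower and 1 higher of 26, was not called (1 higher and 6 lower adjusted over the list alone, adjusted p = 0.14). Mitochondrial genome transcripts fell in 10 of 13 cases with a median of -1.22 (0 higher and 10 lower adjusted over the list alone, adjusted p = 6.3e-09, and adjusted p = 0.090 with an estimated correlation). The number and median were 6 and -0.53 with the GC correction and 0 and 0.15 with the term (list adjusted p = 1.2e-06 and 0.11), in which mt-Cytb went from -1.24 to 0.10. Immunoproteasome and MHC class I genes rose in 10 of 14 cases, H2-K1 by 0.41 ± 0.08, and fell in 2, and with the correction none passed (11 higher and 2 lower adjusted over the list alone, adjusted p = 0.0062, adjusted p = 0.40 with an estimated correlation, and 0.58 with the GC correction). Ribosomal protein genes rose in 2 of 22 cases and 0 with the correction (1 higher and 0 lower adjusted over the list alone, adjusted p = 0.042, adjusted p = 0.78 with an estimated correlation, 0.26 with the GC correction and 0.013 with the term). Mature single positive markers went both ways, 4 higher and 7 lower of 19, with no call (5 higher and 7 lower adjusted over the list alone, adjusted p = 0.27). The log2 fold change of Il7r, -0.85, went to -0.37 with the correction. In all, 2414 genes were higher and 2514 lower (4928 called), and their mean GC content was 55.5% and 42.3%. With the GC correction 923 genes were called (653 shared). With the term, edgeR called 0 genes and 747 passed an unadjusted p under 0.05. The size of the term rests on CD4 SM KO alone, so the values with it decide nothing on CD4 M2 genes. Genotype and library set cannot be told apart in this comparison, and no comparison without the 5 libraries was possible.

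**Figure D2:**
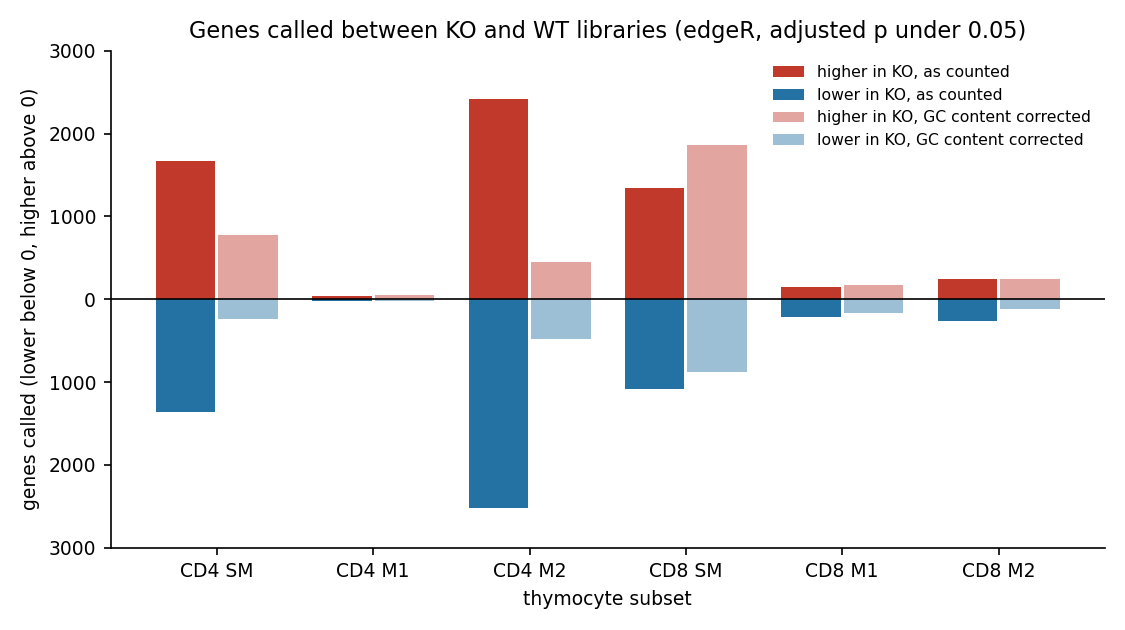
Number of genes higher (above 0) and lower (below 0) in KO libraries by subset, as counted (dark bars) and after the GC content correction (light bars), at an adjusted p under 0.05 in edgeR. The bars for CD4 SM and CD4 M2 shrink from 3029 to 1009 and from 4928 to 923 genes, and those for CD8 SM go from 2429 to 2738. Those for CD8 M1 go from 364 to 335 and those for CD8 M2 from 511 to 364.

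**Figure D3:**
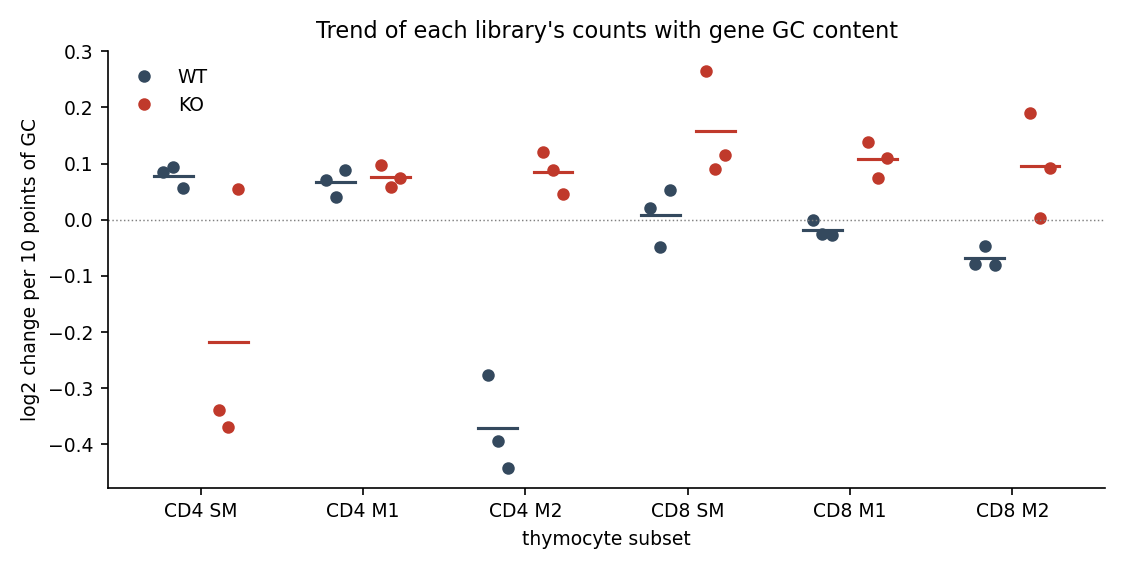
Slope of each library's log2 counts with gene GC content, per 10 percentage points, by subset and genotype, with 1 point per library and a bar at the mean of 3. The 5 libraries below -0.2 are KO replicates 1 and 2 of CD4 SM and the 3 WT libraries of CD4 M2, which run from -0.442 to -0.277, and the other 31 run from -0.080 to 0.266.

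Genes of the heat shock and immediate early responses were higher in KO libraries of several subsets. Hspa1a and Hspa1b, the stress-inducible Hsp70 genes, were higher in all 6 subsets. In CD4 SM they stood at 93.1 ± 114 against 1.78 ± 2.31 CPM (log2 fold change 5.74 ± 1.26, adjusted p = 0.0017) and 157 ± 167 against 4.95 ± 7.21 CPM (5.01 ± 1.19). Reads of these near-identical genes may be split between them. In CD8 SM they stood at 59.99 ± 68.4 against 0.707 ± 1.10 CPM (6.51 ± 1.39) and 119.5 ± 122 against 2.22 ± 2.69 CPM (5.81 ± 1.29). Replicate 3 was the highest of its group in 12 of 12 groups, WT and KO alike, and KO exceeded WT in 18 of 18 ratios of libraries with the same replicate number. Plk2, a kinase induced by stress and by mitogens, was also higher in all 6, with log2 fold changes of 2.05 in CD4 SM and 1.75 in CD4 M1. In CD8 M1 the Hspa1a call was lost without KO replicate 3 or any single WT library (log2 fold change 3.64 to 6.93), as in CD8 M2 (4.03 to 7.02), and in CD4 M1 without any library but KO replicate 2 (4.07 to 7.10). Chaperones rose in 11, 4 and 8 of 30 cases in CD4 SM, M1 and M2 and in 12, 2 and 3 in CD8 SM, M1 and M2. They fell in 6 cases in CD4 M2. Over the list alone 12, 11, 8, 13, 4 and 9 rose in that order. Camera called the chaperones in CD4 SM (12 higher and 0 lower adjusted over the list alone, adjusted p = 6.4e-05, and adjusted p = 0.40 with an estimated correlation), CD4 M1 (4.1e-05 and 0.40), CD8 SM (1.6e-05 and 0.38), CD8 M1 (0.010 and 0.60) and CD8 M2 (8.4e-06 and 0.37). In CD4 M2 they were not called (8 higher and 6 lower adjusted over the list alone, adjusted p = 0.42), but were with the replicate number as a block (6.5e-05) and with the GC correction (2.6e-04). Besides Hspa1a and Hspa1b, the list in CD4 SM held Dnaja1 (475 ± 41.7 against 243 ± 36.02 CPM), Hsp90aa1 (458 ± 72.01 against 247 ± 43.1 CPM) and the mitochondrial chaperonin Hspd1 (274 ± 8.73 against 171 ± 12.05 CPM), and in CD8 SM Hspa8 (1817 ± 349 against 1006 ± 187 CPM). Immediate early genes rose in 9, 4 and 13 of 16 cases in CD4 SM, M1 and M2 and in 9, 9 and 10 in CD8 SM, M1 and M2. Hspa1a and Hspa1b are members of this list too and are in each of these counts. The chaperone and immediate early results are therefore not separate evidence. Of these genes 1, Egr1 in CD4 SM, fell (-0.44 ± 0.15, -0.18 with the GC correction). That call on Egr1 was lost without KO replicate 1, KO replicate 3, WT replicate 1 or WT replicate 2 (log2 fold change -0.40 to -0.29). Camera called them in all 6 subsets, at adjusted p = 5.5e-04, 7.0e-12, 1.7e-06, 1.1e-08, 3.9e-16 and 2.7e-12 in the same order. They had adjusted p = 0.39, 0.063, 0.23, 0.14, 0.026 and 0.059 with an estimated correlation. Dusp1, a phosphatase of this response, rose in CD8 M1 from 108 ± 20.2 to 222 ± 22.7 CPM (1.04 ± 0.16).

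Between the 2 later CD8 subsets, 82 higher and 70 lower genes were called in both M1 and M2, where independent lists would share 2.31 and 3.56. CD8 SM and CD8 M2 shared 137 higher genes (20.6 for independent lists) and 191 lower ones (18.1). Log2 fold changes correlated with gene GC content at 0.20, 0.21 and 0.23 in CD8 SM, M1 and M2, a common trend not taken out of these counts. CD4 SM and CD4 M2 shared 64 higher genes (252 for independent lists) and 19 lower ones (214). A further 1087 genes higher in CD4 SM were lower in CD4 M2, the pair of comparisons that holds the 5 libraries on opposite sides. Libraries with the same replicate number deviated together across the subsets of a genotype (median correlation across genes 0.33, 82 of 90 pairs above 0.1), so calls shared between subsets are not independent evidence.

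**Figure D4:**
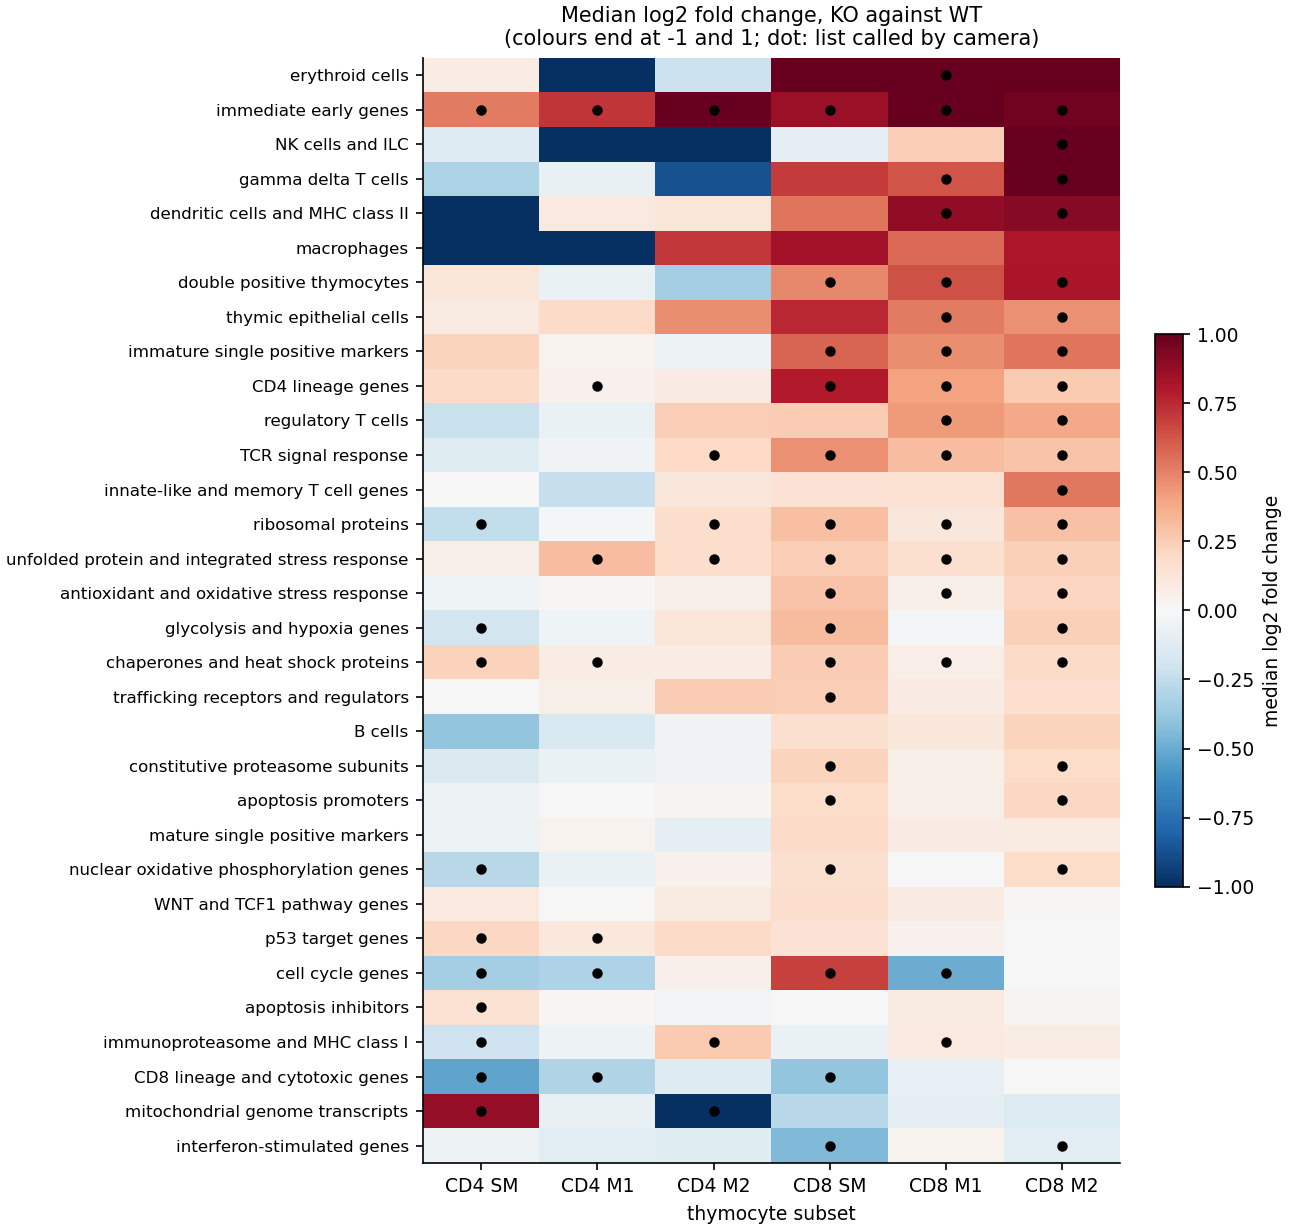
Median log2 fold change, KO against WT, of 32 fixed gene lists (vertical axis) in the 6 subsets (horizontal axis), with colours that end at -1 and 1 and a dot where camera called the list at an adjusted p under 0.05. Dots stand in 77 of 192 cells, and the immediate early genes have one in each of the 6 subsets.

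The other called lists rested on few single genes or none. In CD8 M2 the constitutive proteasome list (median log2 fold change 0.18, adjusted p = 3.7e-05, and adjusted p = 0.48 with an estimated correlation) was called higher. So were the nuclear oxidative phosphorylation (0.19, 1.4e-05 and 0.48), glycolysis (0.24, 7.4e-04 and 0.35) and ribosomal protein lists (0.29, 5.0e-08 and 0.40). No single member of these 4 lists passed the edgeR test over all genes, and the last list had 15 of 22 adjusted over the list alone. In CD8 SM the constitutive proteasome list had 2 of 26 genes higher (13 adjusted over the list alone, adjusted p = 1.9e-05, and adjusted p = 0.48 with an estimated correlation), such as Psmc3 (0.41 ± 0.10). Also called in CD8 SM were ribosomal proteins (0.30, 8.3e-05 and 0.57), nuclear oxidative phosphorylation (0.16, 0.0027 and 0.65) and the unfolded protein response, with 4 higher and 1 lower of 13 (0.039 and 0.36). In CD8 M1 the called lists included the unfolded protein response with 2 higher (0.0014 and 0.14), ribosomal proteins (0.011 and 0.72) and antioxidants (0.045 and 0.48). Others were immunoproteasome and MHC class I (0.036 and 0.51) and thymic epithelial markers (0.013 and 0.059), whose single higher member was Psmb11. The 2 tested erythroid markers (0.045 and 0.32) and the gamma delta markers (0.041 and 0.12) were called higher there too. No single marker of either list rose over all genes (2 of 2 and 2 of 7 adjusted over the list alone), and Cd163l1 fell (2.46 ± 0.522 against 6.13 ± 2.25 CPM, -1.32 ± 0.31). That call was lost without KO replicate 2, KO replicate 3, WT replicate 1 or WT replicate 2 (log2 fold change -1.29 to -1.05). In CD8 M2, apoptosis promoters (0.0023 and 0.052), antioxidants (0.0011 and 0.30) and the unfolded protein response (0.020 and 0.30) were called higher. MHC class II markers (0.0037 and 0.078) and thymic epithelial markers (0.045 and 0.14, again with Psmb11) were too, and interferon-stimulated genes lower (0.0058 and 0.48). Camera at the preset correlation, without the GC correction, called the B cell and macrophage lists in no subset. In CD4 SM fry called the B cell list lower (adjusted p = 0.029). Camera with the GC correction called the macrophage list lower there (adjusted p = 0.042). Cd79b (1.63 ± 0.121 against 3.08 ± 0.306 CPM) and Ighm (53.3 ± 4.56 against 68.7 ± 2.80 CPM) fell singly in CD4 SM (-0.72 and -0.22 with the GC correction, at adjusted p = 0.063 and 0.13). Ighm also fell in CD8 M1 (238 ± 4.15 against 299 ± 10.6 CPM, -0.33 ± 0.08), a call lost without any single library (log2 fold change -0.35 to -0.30). Of the macrophage markers, C1qa (0.0372 ± 0.0361 against 0.561 ± 0.557 CPM) and Lyz2 (0.139 ± 0.124 against 1.21 ± 0.92 CPM) fell in CD4 SM, to levels near or below the 0.127 CPM of 3 counts in the smallest library. With the GC correction they had adjusted p = 0.088 and 0.047, and 0.54 and 0.47 with the term. Both calls were lost without KO replicate 1 or WT replicate 2, that of C1qa also without KO replicate 2 and that of Lyz2 without WT replicate 1 (log2 fold changes -3.74 to -2.53 and -2.75 to -2.53). Cd68 rose in CD4 M2 (7.44 ± 0.579 against 4.36 ± 1.02 CPM, 0.77 ± 0.25, 0.60 at adjusted p = 0.16 with the GC correction), a call lost without KO replicate 1 or WT replicate 1 (0.58 to 0.68). Too few granulocyte markers were tested for camera, and S100a9, at 0 counts in CD8 SM of WT libraries, was the one called there. The call was lost without any of 5 of the 6 libraries. Median or mean differed in sign from the camera direction in 23 of 192 cases, 0 of them called, such as TCR response genes in CD4 SM (median -0.12, tested higher), mature markers in CD4 SM (-0.05, tested higher), CD8 SM (0.19, tested lower) and CD8 M1 (0.08, tested lower) and CD8 lineage genes in CD8 M1 (median -0.08, mean 0.09). The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 to 3 counts in every library, while Xist was read in all of them. Its level was 2266 ± 593 against 1442 ± 95.8 CPM in CD4 SM and 946 ± 38.8 against 1913 ± 569.97 CPM in CD4 M2. In subsets without any of the 5 libraries it was 1370 ± 70.1 against 1497 ± 84.9 CPM in CD4 M1 and 1142 ± 197 against 1471 ± 65.5 CPM in CD8 SM. It was 947 ± 30.4 against 1375 ± 5.28 CPM in CD8 M1 and 810 ± 144 against 1188 ± 44.6 CPM in CD8 M2.

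The difference of the KO effect between the lineages was tested as an interaction at each stage. At M1, Zbtb7b (2.26 ± 0.33, adjusted p = 4.8e-04), Cd4 (1.35 ± 0.17, adjusted p = 8.2e-05) and Myo1e (2.01 ± 0.34, adjusted p = 0.0056) rose more in CD8 than in CD4, as did Rnf216 (1.77 ± 0.31). There 15 genes had a higher and 2 a lower difference (17 called). The replicate numbers pair the libraries of this comparison, and with the replicate number as a block 35 genes were called. The count was 5 without CD8 M1 KO replicate 1, 6 without CD8 M1 WT replicate 1 or WT replicate 3, and 8 without CD4 M1 WT replicate 3. It was 9 without CD8 M1 KO replicate 2 or CD4 M1 KO replicate 3, 10 without CD4 M1 WT replicate 1 and 11 without CD4 M1 KO replicate 1, and with the GC correction it was 9. At M2, Myo1e (3.02 ± 0.36, adjusted p = 1.2e-05), Nrgn (2.44 ± 0.39, adjusted p = 0.0015) and the chemokine receptor Cxcr6 (2.43 ± 0.48) had a more positive effect in CD8. There were 655 higher and 352 lower differences (1007 called, 256 with the GC correction and 3 with the term for the 5 libraries). That count was 385 without CD8 M2 WT replicate 2, 462 without CD4 M2 WT replicate 3, 573 without CD8 M2 WT replicate 1, 580 without CD4 M2 KO replicate 2, 631 without CD4 M2 KO replicate 1 and 661 without CD8 M2 KO replicate 2. At SM, the kinesin Kif2c (2.25 ± 0.39, adjusted p = 2.2e-04, 2.15 with the GC correction) had a more positive effect in CD8 and the zinc finger gene Zfp51 (-2.13 ± 0.29, -1.40 with the correction) a more negative one. There were 2190 higher and 1813 lower differences (4003 called, 1466 with the GC correction and 658 with the term). That count was 2465 without CD8 SM KO replicate 1 and 2591 without CD4 SM KO replicate 1.

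The WT libraries show how the subsets differ by stage. From SM to M1, S1pr1, the receptor by which thymocytes leave the thymus, rose from 2.20 ± 0.178 to 114 ± 14.04 CPM in CD4 (5.69 ± 0.22, adjusted p = 1.8e-20). In CD8 it rose from 0.95 ± 0.188 to 60.5 ± 6.89 (5.98 ± 0.24, adjusted p = 3.0e-20). At M2 it stood at 656 ± 56.3 and 341 ± 25.3. The nonclassical MHC gene H2-Q7 rose in CD8 from 1.38 ± 0.675 to 88.7 ± 26.6 (6.03 ± 0.45), as part of a multigene family whose reads may be split. The chemokine Xcl1 rose in CD8 from 0.394 ± 0.142 to 25.2 ± 3.14 CPM. Zbtb7b fell from 88.9 ± 3.99 to 0.697 ± 0.165 (-6.98 ± 0.23) and Cd4 from 690.1 ± 67.1 to 12.4 ± 1.22 (-5.79 ± 0.15). In CD4, Edaradd fell from 37.3 ± 2.96 to 3.73 ± 1.56 CPM. Pimreg and Pif1, genes of dividing cells, rose from 0.266 ± 0.106 to 13.6 ± 1.40 and from 0.205 ± 0.188 to 10.9 ± 0.74. From M1 to M2, Asb2 fell in CD4 from 18.4 ± 0.746 to 0.507 ± 0.163 CPM (-5.19 ± 0.30, -4.73 with the GC correction and -4.66 with the term). Igfbp4 rose in CD8 from 42.6 ± 4.96 to 497 ± 18.8 (3.54 ± 0.17). Klrd1, a receptor of cytotoxic cells, rose in CD8 from 2.71 ± 0.48 to 34.004 ± 1.13 (3.65 ± 0.31) and Il2ra fell from 5.83 ± 0.323 to 0.662 ± 0.212. From SM to M1, 2238 genes were higher and 2043 lower in CD4 and 3381 and 2903 in CD8, and from M1 to M2 3201 and 3499 in CD4 and 1112 and 1312 in CD8. The M2 libraries of CD4 hold the 5 libraries' 3 WT members. In place of 6700 genes, 5388 were called with the GC correction (3750 shared) and 1324 with the term. With the term Cd55 went from 3.50 to -0.35.

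Between the lineages in WT, coreceptor genes and lineage factors differed. At M1, Cd8a had 2338 ± 47.2 against 12.8 ± 0.871 CPM in CD8 against CD4 (7.52 ± 0.14, adjusted p = 1.6e-30). Also at M1, Itgae had 516 ± 30.4 against 1.43 ± 0.287 CPM, and Nkg7 134 ± 7.83 against 0.726 ± 0.208 CPM. Cd4 had 12.4 ± 1.22 against 1238 ± 24.9 CPM (-6.64 ± 0.15) and Zbtb7b 0.697 ± 0.165 against 417 ± 23.2 CPM (-9.21 ± 0.23, adjusted p = 2.2e-26). At SM, Rag1 (322 ± 20.4 against 4.42 ± 0.219 CPM, 6.19 ± 0.23) and Rag2 (13.5 ± 2.63 against 0.085 ± 0.0177 CPM) were higher in CD8. The growth factor binding protein Igfbp4 (4.98 ± 0.834 against 73.7 ± 3.78 CPM) and the cytokine Il21 (0.573 ± 0.349 against 8.80 ± 1.28 CPM) were higher in CD4. At M2, Cd40lg, the ligand by which CD4 T cells help B cells, had 1.01 ± 0.195 against 74.7 ± 6.12 CPM and Adgrg5 281 ± 18.7 against 2.26 ± 0.461 CPM in CD8 against CD4. Akr1c18 and Robo1 were at 0 counts in CD8. In CD8 against CD4, 1540 genes were higher and 1832 lower at SM, 2470 and 2391 at M1, and 3802 and 4001 at M2. At M2, 7198 genes in all were called with the GC correction (6129 shared) and 3571 with the term. Ccr7 and Klf2, used as stage checks, stood at 338 ± 17.7 and 18.996 ± 3.66 CPM in CD4 SM. They stood at 524 ± 69.5 and 422 ± 28.6 in CD4 M2 of WT libraries. Cd24a went from 119 ± 15.6 to 17.6 ± 0.958.

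Antigen receptor segments were counted as groups, since reads may be split between similar segments. In CD8 SM of KO libraries 6 of 25 TRBV segments were higher and 2 lower, and 5 of 14 TRBJ segments were lower. In CD4 SM 7 of 75 TRAV segments were lower and 1 higher (1 and 1 with the GC correction). Of 25 TRBV segments there, 7 were lower and 1 higher (4 and 0 with the GC correction). With the term edgeR called 0 segments of either kind. In CD4 M2, where the WT libraries are among the 5, 12 of 56 TRAJ segments were lower, 6 with the GC correction (and 1 higher) and 0 by edgeR with the term. In WT, all 14 TRBJ segments tested were lower in M1 than in SM of the CD8 lineage, and 45 of 56 TRAJ segments were lower in CD8 than in CD4 at M2. That last comparison holds 3 of the 5 libraries, and 40 were lower with the GC correction and 7 with the term. At M1, which holds none of them, 11 were lower, and from M1 to M2 of WT CD4 16 were higher (15 with the correction and 0 with the term).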

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

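Chosen only after the results were seen were the GC tests, the term for the 5 libraries, the test of shared reads, the test of a difference between replicate numbers, the M1 splits with the block or with pairs kept together and the tests of other cells in the sort gates. The library size and handling tests and the other tests of splits were written before. For CD4 M1 and CD4 M2 cells in the gates, a looser rule tried first, with the upper quartile of the implied share as the only bound, was replaced by the rule used for CD8 SM cells, and CD4 M2 cells met the looser one. Cd4 was first counted among the genes it was compared with, and leaving it out changed none of these readings.

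The KO effect differed between the lineages by the interaction test for 4003 genes at SM, 17 at M1 and 1007 at M2, each as the CD8 minus the CD4 log2 fold change. At SM these included Aunip (2.73), Hist1h3c (2.65), Ly6c1 (2.56) and Kif2c (2.25), more positive in CD8, and mt-Atp6 (-4.07), Zfp992 (-2.46), Zfp984 (-2.42), Zfp948 (-2.25) and Zfp51 (-2.13), more negative. At M1 they included Zbtb7b (2.26), Myo1e (2.01), Rnf216 (1.77), Nrgn (1.57) and Cd4 (1.35), and Klf8 (-1.43) and Iqgap2 (-0.59). At M2 they included Myo1e (3.02), mt-Atp6 (2.87), Col6a2 (2.62), Nrgn (2.44) and Cxcr6 (2.43), and Stau2 (-2.02), Snora68 (-1.75), Cd163l1 (-1.44), Col7a1 (-1.42) and Klhdc8b (-1.31). Without single libraries the calls were lost for Hist1h3c (2.27 to 2.40) and Ly6c1 (2.04 to 2.18) at SM, and for Iqgap2 (-0.60 to -0.54), Klf8 (-1.52 to -1.32) and Nrgn (1.33 to 1.68) at M1. At M2 they were lost for Cd163l1 (-1.46 to -1.06), Col6a2 (2.05 to 2.67), Col7a1 (-1.34 to -1.17), Stau2 (-2.04 to -1.54) and mt-Atp6 (2.62). With the GC correction 1466 differences were called at SM and 256 at M2, and with the term for the 5 libraries 658 and 3. With the term the difference of mt-Atp6 was -1.43 at SM and -0.28 at M2.

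Other splits of the same libraries were compared with the real one. For the interactions, fitted on their own libraries alone, 100 splits were drawn. At SM, 1 gave as many genes, the real one (2891 against at most 987 in the others), a share under 0.05. The split with 987 kept KO and WT of CD8 SM whole and held KO replicates 1 and 2 of CD4 SM, which are among the 5, together. The draws did not keep the WT pairs between the lineages at SM, so this share does not exclude chance. At M1, 7 gave as many without the replicate block (86 against up to 626), so chance cannot be excluded in that fit, and with the block 2 did (410 against 853), a share under 0.05. The other splits as large, with or without the block, kept KO and WT of CD8 M1 whole and mixed those of CD4 M1, so the KO effect in CD8 was still in them. The M1 libraries pair between the lineages, and the 10 splits that keep each pair together are too few for a share under 0.05. The real and the highest other count in these were 410 and 1 with the block and 86 and 0 without. At M2, 4 gave as many (873 against up to 2927), a share under 0.05. The 3 others kept KO and WT of CD4 M2 whole, which also keeps the 3 WT libraries among the 5 together, and mixed those of CD8 M2. The draws did not keep the KO pairs between the lineages at M2, so the share there does not exclude chance either. For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real and the highest other count, fitted on those libraries alone, were 663 and 0 in CD4 SM, 3064 and 0 in CD4 M2, 2252 and 0 in CD8 SM, 1788 and 1 in CD8 M1 and 779 and 1 in CD8 M2, with 1 split of 10 as large in each. In CD4 M1 edgeR called 0 genes in all 10 splits (1309 at an unadjusted p under 0.05 in the real one, and 123 by DESeq2 over all libraries). The stage counts were 4836, 5549, 7954 and 4106, the lineage counts 4806, 5865 and 7408, and the highest other was 0 in each. The list calls were 77 against at most 51, also over 10 splits, too few for a share under 0.05. The split with 51 mixed KO and WT libraries, so list calls at the preset correlation can arise without the full genotype contrast.

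The counts of called genes were largest in CD4 M2 (4928) and CD4 SM (3029), the subsets with the 5 libraries whose counts fell with gene GC content. A difference in library size was argued against, since the ratio of KO to WT gene counts was 1.02 in CD4 M2 and 0.960 in CD4 SM. GC dependent counting may account for much of both counts: with each library scaled along its own GC trend, 923 and 1009 genes were called. In CD4 M2 a genotype effect cannot be told apart from the library set, since all 3 WT libraries are among the 5. With a term for the 5, edgeR called 0 genes there (747 at an unadjusted p under 0.05). That term rests on CD4 SM KO alone, so this count decides nothing. A genotype effect in CD4 SM stays open, with 784 of the calls kept under the GC correction.

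Hspa1a, Hspa1b and immediate early genes were higher in KO libraries. GC dependent counting was argued against, since 12 of 12 tests of Hspa1a and Hspa1b stayed past the threshold with the correction. Besides that pair, 9 other chaperones were called higher in at least 2 subsets, so the rise of chaperones was not that of the pair alone. Whether reads are shared within the pair cannot be told from the other chaperones and stays open. The test of a difference between replicate numbers that both genotypes share decides nothing. Each number is in both genotypes of every subset, so such a difference cannot separate KO from WT. KO exceeded WT by 3.78 to 7.09 on the log2 scale in 36 of 36 ratios of Hspa1a and Hspa1b between libraries with the same number. Every KO library lay above every WT library of its subset for both genes, so any pairing gives positive ratios. The 16 immediate early genes, Hspa1a and Hspa1b among them, had medians of 0.79 to 0.87. A handling or animal difference that goes with genotype stays open, since no label records handling. The 54 genes higher in at least 4 subsets, with Psmb11 left out, were compared within WT. WT replicate 3 lay above WT replicates 1 and 2 by a median of 0.169 on the log2 scale (47 of 54 above 0). That value lay between the bounds set for it (over 0.2 if the cause, 0 or less if not). An effect of genotype on the cells cannot be told apart from such handling and was not tested.

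CD4 lineage genes were higher in KO libraries of the CD8 subsets, and the list stayed called with the GC correction in 3 of 3, which argues against GC dependent counting. In CD8 SM, CD4 SM cells in the gate were argued against as the whole cause of the KO difference: such cells hold little Rag1, which rose by 0.83. Whether they add to the rise of Cd4 stays open. Double positive thymocytes in this gate, whose markers also rose, were not tested as a cause. The rise in CPM, over the KO level in CD4 SM, was 46.0% for Cd4. It had a median of 12.9% over 27 genes at least 4 times higher in WT CD4 SM, and was above 0 in 26 of them. For Cd4 this is no share of cells and decides nothing, since WT CD8 SM already held 690 CPM. Cd4 in KO CD8 SM stood at 1234 ± 76.1 CPM, beside 1183 ± 13.7 CPM in KO CD4 SM. In CD8 M1, a small share of other cells is a candidate explanation for the rise of Cd4. The share implied by Cd4 was 1.58% of CD4 M1 cells or 1.63% of CD8 SM cells. Both lay within the quartiles over 9 other genes of each (0.723 to 2.69% and 1.36 to 2.33%). The shares implied by Zbtb7b, 0.647% and 1.18%, lay below these quartiles. Zbtb7b is itself among the 9 genes of each, so for Zbtb7b the values decide neither. The rise of Rag1 would need a share of 336% of CD4 M1 cells, so such cells were argued against as the source of that rise. Rag1 is not in the CD4 lineage list, so this decides nothing on the rise of Cd4. For CD8 SM cells the Rag1 share was 1.36%. Rag1 is itself among the 9 genes and sets their lower quartile, so this value decides nothing. In CD8 M2 the share from Cd4 lay below the lower quartile over 9 other genes for CD4 M2 cells (0.395% against 0.486 to 2.26%) and over 28 for CD8 SM cells (0.374% against 0.496 to 3.08%), so the values decide neither. A change in lineage choice in KO thymocytes stays open as a hypothesis.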

How the results depend on the processing

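The GC content correction, alone and with the replicate block, the term for the 5 libraries and the fits without them were chosen only after the results were seen, and the other alternatives were planned. Of 8200 values of named genes under an alternative, 6772 kept their direction and their call, 1382 kept the direction and lost the call, and 46 turned. DESeq2 kept 504 of 504 calls of named genes, RLE size factors 506 of 512 and RSEM counts 451 of 511. The cause of the changes below was not tested, except that fits on the compared libraries alone, or without libraries, hold fewer samples.

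With only the libraries of the groups compared, the called genes were 663 in CD4 SM (3029 in the model of all libraries), 3064 in CD4 M2 (4928), 1788 in CD8 M1 (364), 779 in CD8 M2 (511), 86 for the M1 interaction (17) and 4106 for M2 against M1 in WT CD8 (2424). In CD4 M1 edgeR then called 0 in place of 52 (1309 at an unadjusted p under 0.05, and 123 by DESeq2). With no filter on low counts they were 297 in CD4 M1, 777 in CD8 M1, 1147 in CD8 M2 and 116 for the M1 interaction. With RSEM expected counts they were 7 in CD4 M1. With the DESeq2 Wald test they were 123 in CD4 M1, 584 in CD8 M1, 976 in CD8 M2 and 33 for the M1 interaction.

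With the replicate number as a block they were 81 in CD4 M1, 35 for the M1 interaction and 1726 for the M2 interaction. Where the numbers pair libraries, the block changed that M1 interaction and, in CD4 M2, the chaperone list (adjusted p 0.42 without and 6.5e-05 with it) and the calls of Ctnnb1 (-0.19) and Trdc (-0.34), which were lost with the same log2 fold changes, and no other call on a named gene or list. Where the numbers do not pair them, 14 calls of named genes were lost with the block, 5 list calls were gained and 2 were lost. With the GC content correction and the replicate block they were 883 in CD4 SM, 122 in CD4 M1, 848 in CD4 M2, 2629 for the SM interaction and 48 for the M1 interaction. With the GC content correction alone they were 1009 in CD4 SM, 923 in CD4 M2, 1466, 9 and 256 for the SM, M1 and M2 interactions.

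With the term for the 5 libraries they were 176 in CD4 SM, 928 in CD8 M2, 658 and 3 for the SM and M2 interactions, 1324 for M2 against M1 in WT CD4 and 3571 for CD8 against CD4 in WT M2. In CD4 M2 edgeR called 0 (747 at an unadjusted p under 0.05). Without the 5 libraries they were 221 in CD4 SM (1 KO library, assumed to vary like the other groups), 101 in CD4 M1, 647 in CD8 M1, 1305 in CD8 M2 and 1559 for the SM interaction. No fit without them was possible for comparisons with CD4 M2 of WT. Of 77 list calls, 18 held with an estimated correlation.

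Without 1 library at a time, the called genes ran from 1073 to 4461 in CD4 SM, 0 to 161 in CD4 M1 (0 by edgeR without KO replicate 1, with 1112 at an unadjusted p under 0.05), 3530 to 5033 in CD4 M2, 885 to 2398 in CD8 SM, 100 to 218 in CD8 M1 and 113 to 1206 in CD8 M2. The interactions ran from 2465 to 5060 at SM, 5 to 16 at M1 and 385 to 1365 at M2. M1 against SM ran from 3530 to 3859 in WT CD4 and 5157 to 5576 in WT CD8, M2 against M1 from 5424 to 6784 and 1911 to 2018, and CD8 against CD4 in WT from 2578 to 2889 at SM, 3768 to 4459 at M1 and 6566 to 8042 at M2. Without all libraries of replicate number 1, 2 or 3, list calls were 79, 74 and 72. Of the 77 list calls, 68, 66 and 63 were then kept. Of named genes, 42 of 96 kept their call without any 1 library in CD4 SM, 0 of 23 in CD4 M1, 77 of 99 in CD4 M2, 68 of 96 in CD8 SM, 15 of 46 in CD8 M1 and 20 of 57 in CD8 M2.

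With the term, log2 fold changes turned in CD4 SM for Api5 (0.37 to -0.0125), mt-Cytb (0.82 to -0.19), mt-Nd2 (1.27 to -0.23) and mt-Nd5 (0.95 to -0.17), and without the 5 libraries for Api5 (-0.0129), mt-Cytb (-0.19), mt-Nd2 (-0.23) and mt-Nd5 (-0.18). With the term they turned in CD4 M2 to 0.11 for Api5, 0.0310 for Canx, 0.52 for Ccne2, 0.11 for Ccng1, -0.0434 for Cd5, -0.28 for Cldn4, 1.4e-05 for Ctnnb1, 0.0456 for Gbp2, -0.17 for Il2rb, 0.12 for Il7r, 0.35 for Klrd1, 0.0208 for Ms4a6b, 0.15 for mt-Atp6, 0.10 for mt-Cytb and 0.36 for mt-Nd2. They also turned there to 0.0771 for Psma1, 0.19 for Psmd14, -1.96 for Rhob, 0.0696 for Trdc, 0.12 for Xiap, 0.73 for Zfp820 and 0.56 for Zfp984. The M2 interaction of mt-Atp6 turned to -0.28, and Cd55 between M2 and M1 in WT CD4 to -0.35. Every WT library of CD4 M2 carries the term, whose size rests on CD4 SM KO alone. Turns in comparisons with CD4 M2 of WT therefore decide nothing on those genes. With the GC content correction Psmc6 turned in CD4 SM (-0.0605, and -0.0635 with the replicate block). In CD4 M2 it turned Bax (-0.0629, and -0.0617 with the block), Cd5 (-0.0208 and -0.0193), Ms4a4b (0.0299 and 0.0353), Psmc6 (0.19 and 0.22), Runx3 (-0.0035 and -0.0099) and Xiap (0.12 and 0.13).

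Depth limits genes near the floor of 0.0755 to 0.127 CPM, such as Psmb11 in WT libraries.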

Other observations

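The test of calls near the targeted gene was written before its result was seen, and the counts of genes shared between subsets were not planned as tests. Across subsets, 18 genes were higher in KO libraries in at least 5 of the 6, among them the growth arrest genes Btg2, Gadd45a and Tob1, the signal regulators Rgs1, Rgs2, Spry2 and Dusp1, and the transcription regulators Klf4, Fos, Nr4a1, Cited2 and Tgif1. In at least 4 subsets 55 genes were higher and 37 lower, and Kcna2, a potassium channel gene, was the 1 gene lower in at least 5. Since libraries with the same replicate number deviated together across subsets, these counts are not independent evidence.

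A segment of another strain around the targeted gene was tested as a source of calls: genes within 10 Mb of Psmb11 on chromosome 14 were called in at least 2 CD8 subsets at 0.967 times the share elsewhere (9 of 326 against 447 of 15654), which argues against such a segment as a source of many calls.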
